A study of Mus musculus with 7 samples.

How the data were processed

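RNA of mouse tissue was measured on 7 Affymetrix Mouse Gene 1.0 ST arrays: Iqgap1 knockout at day 0 (n = 2) and day 6 (n = 2), and wild type at day 0 (n = 1) and day 6 (n = 2) of topical 4OHT. Per the labels' protocols, RNA was extracted with an RNeasy kit after maceration of the tissue, amplified with a MessageAmp III kit and labelled with biotin. The deposited values are log2 expression values, made by the authors with RMA in R 2.11.1 per the submitters' processing notes; the scale was read from their range, 2.37 to 13.38. RMA subtracts background, normalizes arrays to one another by quantiles and summarizes probes on the log2 scale, so low values are compressed and fold changes of weakly expressed genes are understated. Other settings of RMA, and the batch of each array, were not given in the sources used here. Array counts, not sequencing depth, limit the precision. Groups and replicate numbers came from the sample titles.

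The value table had 34760 probe sets. The platform's gene table listed 22961 of them, 21640 with 1 gene symbol and 1321 with several; 11799 had none and stayed unnamed. Each gene was measured by 1 probe set that names it alone, and of several by the one with the highest mean over the 7 arrays, which gave 19937 genes. Of these, 19855 were matched by gene identifier to the RefSeq genes of GRCm38.p6, which changed 0 symbols. That table served only for names and for which genes neighbour each other, since the sources named no genome build, and no coordinates are given. Probe sets with no gene or several were used only in the setting with all probe sets. Members of gene families with near-identical copies (Sprr2, Lce3, Stfa, Defb, Krtap) can share probes, and their values are uncertain to that extent.

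Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend or robust options), two-sided, with Benjamini-Hochberg adjustment over 19937 genes and a threshold of 0.05. The change with day over both genotypes and the difference between genotypes over both days came from an additive fit of genotype and day (4 residual degrees of freedom). The 5 other comparisons (day within each genotype, genotype within each day, and the difference between genotypes in the day change) came from 1 fit of 4 group means (3 residual degrees of freedom). In that fit the single wild-type day 0 array borrows its error from the other groups. Standard errors use limma's moderated variances. Fold changes are differences of log2 values.

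There were 28 gene lists with 498 members, fixed before the data were examined, from textbook knowledge of skin, of Ras-ERK signalling and of other cell types that skin and the tissue under it hold. Of the members, 453 were measured and the others were not used here. Lists with 5 or more measured members were tested (27). Egr2 and Thy1 each stand in 2 lists. Lists were tested with camera at a preset correlation of 0.01 and, as an alternative, with a correlation estimated from the residuals; adjustment was over the 27 lists of a comparison. No list call of any of the 7 comparisons held with an estimated correlation. This includes lists whose estimate lay below the preset correlation, such as mast cell genes for genotype at day 6 (-0.068). There the loss of a call does not come from correlated members. With an estimated correlation camera uses the residual degrees of freedom of the fit (3 or 4). With the preset correlation it uses nearly the number of genes. Few degrees of freedom raise p at any correlation. A call lost with an estimated correlation therefore does not by itself show correlated members, nor does it show the call to be sound. The rotation test fry was also run: its one-way p asks whether a list's genes move on balance one way, its mixed p whether they change in either direction, and neither compares a list with other genes. List tests for the day change in each genotype and for day 0 were added after the data were examined.

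The named genes followed a rule set before the data were examined. Iqgap1, Iqgap2 and Iqgap3 are always named. For the day change over both genotypes, the 12 largest rises and 12 largest falls past the threshold are named, where all day 6 arrays lie on one side of all day 0 arrays. For knockout against wild type at day 6 it was the 10 largest of each with arrays that do not overlap, and for the other comparisons the 5 largest of each. Where fewer than 5 genes pass, those and the 5 smallest p are named. From each list up to 4 members with the smallest p are named. Predicted genes, small RNAs and receptor families with near-identical copies count in totals but are not named.

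The procedure was tested on simulated data with 200 changed genes among 19937, in 10 simulations per comparison. For the day change over both genotypes 85.2% of 2-fold and 99.6% of 4-fold changes were recovered, and 5.95% of calls were false. Recovery of 2-fold changes was 88.5% for genotype over both days, 53.1% for the day change in knockout, 22.5% for that in wild type and 21.8% for genotype at day 0. The simulated arrays held no difference between genotypes in the day change, while 619 real genes passed for it. Recovery by the additive fit of genotype and day may therefore be overstated. Camera called a list shifted 2-fold in 10 of 10 simulations, and in 10 of 10 with an estimated correlation, with genes simulated independently; with the preset correlation it also called 3 lists that were not shifted.

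The alternatives were a fold of 2 or more as well, thresholds of 0.01 and 0.10, all probe sets, the mean of a gene's probe sets, only genes above the median level, renewed quantile normalization, centring on expressed genes, a variance trend, robust variance, array weights, fits of the compared groups alone, averages of the group-mean differences, the replicate number as a block, and leaving out each array. A term for the 2 arrays with a log2 Xist value above 8, and leaving them out, were added after the data were examined. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.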

Results

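RNA levels were measured in tissue of Iqgap1 knockout and wild-type mice at day 0 and day 6 of topical treatment with 4OHT (4-hydroxytamoxifen, a ligand used to switch on tamoxifen-dependent proteins). Iqgap1 encodes a scaffold protein that binds several kinases of the Ras-ERK cascade, and the series title concerns blocking that binding in Ras-driven tumours. The labels named the tissue only as mouse tissue, from mice of a mixed strain background, and named no inducible protein. There were 7 arrays in 4 groups: 2 of knockout at day 0, 1 of wild type at day 0, 2 of knockout at day 6 and 2 of wild type at day 6. Each array gave log2 RMA values for 34760 probe sets, from which 19937 genes were tested. Array medians over all probe sets lay between 5.61 and 5.79. Pearson correlations across genes, which are not independent replicates, were 0.979 to 0.991 within groups and 0.910 to 0.992 between groups. The first principal component held 53.7% of the variance and parted day 6 from day 0. The next component held 30.8% and set the wild-type day 0 array (-90.3) apart from the other 6 arrays (-16.6 to 26.7). The labels did not say whether replicates came from separate mice, so p-values measure the spread between these samples, which may be technical in knockout. Replicate 1 of wild type at day 6 had Xist signal without Y-linked signal, and replicate 2 the reverse, as given below. The same mouse cannot have given both of these samples.

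Iqgap1 signal was lower in every knockout array than in every wild-type array. The log2 value was 9.02 and 8.99 in the knockout arrays of day 0 and 9.94 in the wild-type array of that day. At day 6 it was 8.63 ± 0.06 (SD, n = 2) in knockout and 10.35 ± 0.34 (SD, n = 2) in wild type. The knockout level at day 6 was 3.31-fold lower, a log2 difference of -1.73 ± 0.20 (SE), and this gene had the smallest p of all genes tested. The limma adjusted p was 0.503, so Iqgap1 did not pass the threshold at day 6; over 20 settings the adjusted p ranged from 0.0514 to 1. The position of the probe set relative to the deleted part of the gene was not used here, so the remaining signal in knockout arrays says nothing about residual transcript. Iqgap2 had 8.57 ± 0.10 (SD, n = 2) in knockout and 6.72 in the single wild-type array at day 0, and 7.21 ± 0.55 and 7.19 ± 0.43 (SD, n = 2 each) at day 6. Iqgap3 had 5.59 ± 0.34 (SD, n = 2) in knockout and 6.02 in wild type at day 0, and 7.28 ± 0.81 and 6.60 ± 0.79 (SD, n = 2 each) at day 6.

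**Figure D1:**
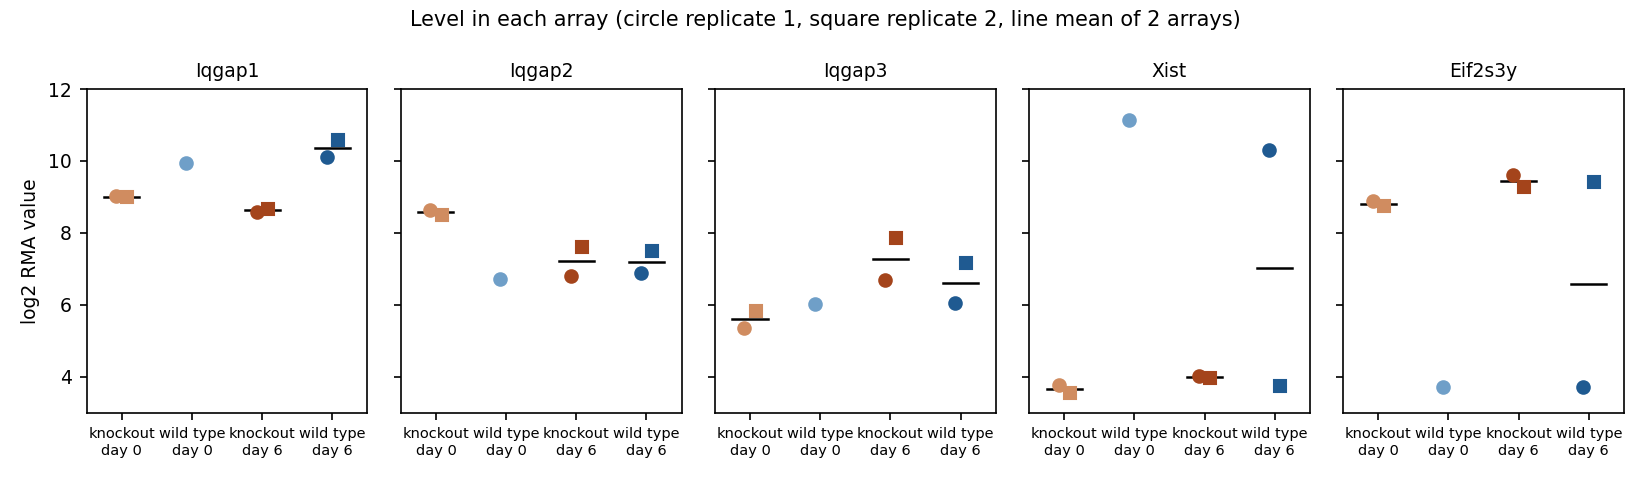
The log2 RMA value (vertical axis) of Iqgap1, Iqgap2, Iqgap3, Xist and Eif2s3y in each of the 7 arrays, by group (horizontal axis); circles are replicate 1, squares replicate 2, and lines the mean where a group has 2 arrays. Iqgap1 lies at 9.02 or below in the 4 knockout arrays and at 9.94 or above in the 3 wild-type arrays, and both wild-type replicate 1 arrays have Xist above 10 with Eif2s3y at 3.72.

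Xist, the RNA of the inactive X chromosome, was chosen for a check of the arrays after its values were seen. It stood at 11.15 and 10.30 in wild-type replicate 1 of day 0 and day 6, and between 3.55 and 4.03 in the other 5 arrays. The Y-linked genes Eif2s3y, Kdm5d and Uty went the other way, with Eif2s3y at 3.72 in each of those 2 arrays and at 8.74 to 9.61 in the other 5. The same 2 arrays had a narrower spread of values over all probe sets (SD 2.404 and 2.385, against 2.446 to 2.492). This split therefore fell within wild type and not within knockout. At day 0 the single wild-type array had Xist signal and both knockout arrays had Y-linked signal. Genotype at day 0 therefore cannot be told apart from this split. The day 6 against day 0 change in knockout, and knockout against wild-type replicate 2 at day 6, lay within the 5 arrays without Xist signal, so list medians within those arrays are given beside printed list medians of these 2 comparisons where a call was lost or gained or the median turned.

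The first comparison asked what changed between day 0 and day 6 over both genotypes (n = 3 and 4 arrays). The largest rise was that of Tmprss11b, a membrane serine protease of surface epithelia, by a fitted log2 fold change of 6.96 ± 0.15 (SE). Its day 0 values, 3.94 to 4.24, lay within the level of Xist and the Y-linked genes in arrays without their signal (3.498 to 4.245), and the day 6 values of Skint10 lay at or under it. The lower group of Lce3e, Lce3a, Csta3, Stfa2, Lep, Serpina3b, Mylk4 and Dsg4 reached it in at least 1 array. Detection calls were not used here, so such changes have no exact fold, and the order of large changes is that of fitted values. Lce3e and Lce3a, which encode late cornified envelope proteins, rose by 6.42 and 5.88, and Defb14 and Defb3, which encode antimicrobial defensins, rose 59.5-fold and 44.6-fold. The largest fall was that of Krt77, a keratin, which was 77.3-fold lower at day 6 (-6.27 ± 0.24, SE). Genes of fat and muscle were among the other large falls: Lep, the fat hormone leptin, was lower by 5.81 on the log2 scale and Pvalb, a calcium-binding protein of fast muscle, was 28.8-fold lower.

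Of 19937 genes, 2286 changed at a limma adjusted p under 0.05, of which 1166 rose and 1120 fell. The other genes among the 12 largest rises were the cystatin genes Csta3 (6.21 on the log2 scale), Stfa2 (5.93) and Stfa3 (5.63), the cornified envelope genes Sprr2d (5.92), Sprr2i (5.45) and the pseudogene Sprr2j-ps (5.41), and Tslp (5.80), an epithelial cytokine. Their adjusted p lay between 3.72e-05 (Sprr2i) and 0.00146 (Stfa3). The other genes among the 12 largest falls were Serpina3b (-5.93), Mylk4 (-5.37), the fat hormone Adipoq (-4.80), the muscle growth inhibitor Mstn (-4.65), Skint10 (-4.60), Mt4 (-4.33), the muscle calcium store protein Casq1 (-4.31), the desmosome gene Dsg4 (-4.31) and Hjv (18.3-fold lower). Their adjusted p lay between 4.60e-05 (Serpina3b) and 0.0227 (Dsg4). The naming rule itself required that the 4 day 6 arrays of these genes lie on one side of the 3 day 0 arrays. Iqgap1 (-0.06 ± 0.21), Iqgap2 (-0.63 ± 0.42) and Iqgap3 (1.24 ± 0.42, SE) did not pass. The Sprr2, Lce3, Stfa and Defb genes have close relatives, and signal may be shared between their probe sets.

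Among keratinocyte groups, 19 of 26 small proline-rich and late cornified envelope genes rose and 0 fell (22 rose adjusted over the list alone). Their median log2 fold change was 2.35, with a camera adjusted p of 9.28e-20 and an adjusted p = 0.152 with an estimated correlation. Sprr2g (5.27 ± 0.18) and Lce3f (5.10 ± 0.21, SE) were further examples. Of 21 hyperproliferative keratinocyte and alarmin genes, 17 rose and 1 fell (18 and 1 adjusted over the list alone), including S100a8 (4.23 ± 0.30), an alarmin of stressed epithelium, and the protease inhibitor gene Slpi (4.62 ± 0.33, SE). The median was 3.85 (adjusted p = 1.19e-13, and adjusted p = 0.328 with an estimated correlation). Of 17 suprabasal differentiation genes, 3 rose and 1 fell (4 and 1 adjusted over the list alone; median 0.32). Dsg1b, Casp14 and Tgm1 rose by 1.55 ± 0.13, 1.99 ± 0.21 and 0.95 ± 0.14, while the filaggrin relative Flg2 changed by -3.67 ± 0.57 (SE). Camera gave an adjusted p = 0.0327, and an adjusted p = 0.397 with an estimated correlation; without the arrays with Xist signal the median was 0.17 (adjusted p = 0.235). Of 15 basal keratinocyte genes, 4 rose and 1 fell (8 and 3 adjusted over the list alone; median 0.72). Sox15 (2.83 ± 0.34), Cdh3 (1.70 ± 0.31) and Lama3 (1.67 ± 0.22) rose, and Krt15, a keratin of hair follicle stem cells, changed by -3.47 ± 0.30 (SE). Camera gave an adjusted p = 0.0191, and an adjusted p = 0.497 with an estimated correlation; without those arrays the median was 0.21 (adjusted p = 0.394).

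Groups of cell division and sugar use were also higher at day 6. Of 23 mitosis genes, 9 rose and 0 fell (21 rose adjusted over the list alone), with Cdc20 at 2.19 ± 0.35, Birc5 at 1.62 ± 0.30 and Foxm1 at 1.61 ± 0.33 (SE). The median was 1.77 (adjusted p = 2.42e-09, and adjusted p = 0.397 with an estimated correlation). Of 24 DNA replication genes, 8 rose and 0 fell (18 rose adjusted over the list alone; median 1.06), with Rrm2 at 1.95 ± 0.35 and Mcm4 at 1.40 ± 0.27 (SE). For these genes adjusted p = 7.18e-08, and adjusted p = 0.397 with an estimated correlation. In knockout 22 of them rose (median 1.56), while in wild type, against its single day 0 array, 0 did and the list did not pass (median 0.29, adjusted p = 0.0623). At day 0 the list mean was 6.93 and 7.17 in knockout and already 8.35 in that wild-type array. Of 14 glycolysis and hypoxia genes, 8 rose and 0 fell (11 rose adjusted over the list alone; median 1.15), with Car9 at 3.82 ± 0.27 and the oxygen sensor Egln3 at 2.27 ± 0.15 (SE). Camera gave adjusted p = 5.60e-08, and adjusted p = 0.328 with an estimated correlation.

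Of the Ras-ERK groups, 5 of 16 ERK feedback regulators and output genes rose and 0 fell (5 and 1 adjusted over the list alone; median 0.49). Spred3, Etv4, Phlda1 and Ccnd1 rose by 2.63 ± 0.33, 1.98 ± 0.30, 1.23 ± 0.22 and 1.00 ± 0.17 (SE). Camera gave adjusted p = 0.0148, and adjusted p = 0.497 with an estimated correlation. In knockout the median was 0.16 (adjusted p = 0.4025, and adjusted p = 0.340 without the arrays with Xist signal). In wild type, against its single day 0 array, it was 0.89 (adjusted p = 1.96e-05, and adjusted p = 0.269 with an estimated correlation). Of 17 IQGAP family and Ras-ERK cascade genes, Map2k1 (0.87 ± 0.16) and Shc1 (0.63 ± 0.15, SE) rose and 0 fell (2 and 0 adjusted over the list alone; median 0.10, adjusted p = 0.223, and adjusted p = 0.684 with an estimated correlation). Of 7 EGF family ligands, Hbegf (4.31-fold) and Tgfa (2.53-fold) rose and 0 fell (3 rose adjusted over the list alone). The median was 0.35 (adjusted p = 0.280, and adjusted p = 0.679 with an estimated correlation). In knockout it was -0.42 (adjusted p = 0.741, and adjusted p = 0.439 without the arrays with Xist signal). In wild type it was 1.1996 (adjusted p = 0.00312, and adjusted p = 0.222 with an estimated correlation). Of 21 immediate-early genes, 2 rose and 5 fell (likewise adjusted over the list alone), with Ier3 at 1.12 ± 0.22 and with Fosb, Atf3 and Nr4a1 at -3.84 ± 0.38, -2.73 ± 0.32 and -2.61 ± 0.41 (SE). That list did not pass (median -0.07, adjusted p = 0.0946, and adjusted p = 0.679 with an estimated correlation). Without the arrays with Xist signal it passed, with a median of -0.44 (adjusted p = 0.00278, and adjusted p = 0.578 with an estimated correlation).

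Groups of fat, muscle and sebaceous glands were lower at day 6. Of 19 skeletal muscle genes, 15 fell and 0 rose (18 fell adjusted over the list alone), with the muscle creatine kinase gene Ckm at -1.60 ± 0.16 and Mylpf at -2.90 ± 0.26 (SE). The median was -1.88 (adjusted p = 2.16e-17, and adjusted p = 0.331 with an estimated correlation). Of 15 adipocyte genes, 12 fell and 0 rose (13 fell adjusted over the list alone; median -1.56), with Retn at -3.80 ± 0.40 and the lipid droplet gene Plin1 at -3.29 ± 0.37 (SE). The list had an adjusted p = 2.38e-13, and an adjusted p = 0.328 with an estimated correlation. Of 15 sebaceous gland genes, 6 fell and 0 rose (7 fell adjusted over the list alone; median -1.95), with Mc5r at -3.75 ± 0.44 and Scd3 at -3.45 ± 0.77 (SE). The list had an adjusted p = 2.62e-06, and an adjusted p = 0.380 with an estimated correlation. Its day 6 means were 6.71 and 7.40 in replicate 1 of knockout and wild type and 8.75 and 8.69 in replicate 2, and its median was -1.12 without knockout day 6 replicate 1. Of 19 fibroblast and collagen genes, 6 fell and 0 rose (8 fell adjusted over the list alone; median -0.62), with Fap at -2.65 ± 0.35 and Dpt at -1.98 ± 0.21 (SE). The list had an adjusted p = 2.62e-06, and an adjusted p = 0.397 with an estimated correlation; its median was -1.16 without the arrays with Xist signal. Of 9 Schwann cell and nerve genes, 4 fell and Mal rose (5 and 1 adjusted over the list alone; median -0.84, adjusted p = 0.000665, and adjusted p = 0.380 with an estimated correlation; -0.50 without knockout day 6 replicate 1). Of 15 endothelial genes, Emcn rose by 0.80 ± 0.14 (SE) and 0 fell (1 and 0 adjusted over the list alone), and the list did not pass (median 0.18, adjusted p = 0.465, and adjusted p = 0.860 with an estimated correlation; -0.18 with adjusted p = 0.170 without the arrays with Xist signal).

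Among immune groups, 6 of 13 Langerhans and dendritic cell genes fell and 0 rose (7 fell adjusted over the list alone; median -1.43). Cd207, the Langerhans cell lectin, was at -2.63 ± 0.24 and H2-Ab1 at -1.99 ± 0.35 (SE), and the list had an adjusted p = 5.97e-05, and an adjusted p = 0.397 with an estimated correlation. Of 15 T cell genes, 4 fell and 1 rose (likewise adjusted over the list alone), with Cd3g at -1.59 ± 0.21 and Cd5 at 1.02 ± 0.17 (SE; median -0.21, adjusted p = 0.0173, and adjusted p = 0.394 with an estimated correlation; -0.13 without knockout day 6 replicate 1). Of 16 interferon-stimulated genes, Gbp3, Ifit3 and Ifit1 fell and 0 rose (5 fell adjusted over the list alone; median -0.73, adjusted p = 3.89e-05, and adjusted p = 0.461 with an estimated correlation). The mean of that list was 7.91 in knockout day 0 replicate 2, against 6.68 in replicate 1 and 6.09 in the wild-type array of that day; without that replicate 2 the median was -0.47. Of 23 inflammatory cytokine and chemokine genes, 7 rose and 2 fell (13 and 3 adjusted over the list alone; median 1.13), with Cxcl3 at 3.56 ± 0.47, Il1a at 2.03 ± 0.28 and Ccl7 at -3.12 ± 0.40 (SE). The list had an adjusted p = 0.00123, and an adjusted p = 0.394 with an estimated correlation, and no longer passed without the wild-type day 0 array (adjusted p = 0.0678). Of 16 macrophage and monocyte genes, 0 rose and 0 fell, over the list alone too (median -0.20, adjusted p = 0.134, and adjusted p = 0.684 with an estimated correlation); without the arrays with Xist signal the list passed (median -0.53, adjusted p = 0.00832, and adjusted p = 0.722 with an estimated correlation), but not in knockout without its day 6 replicate 1 (-0.10, adjusted p = 0.370). Of 10 mast cell genes, Tpsab1 rose by 1.36 ± 0.25 (SE) and 0 fell (2 and 2 adjusted over the list alone; median 0.05, adjusted p = 0.892, and adjusted p = 0.939 with an estimated correlation), and the list's test pointed down while its median was above 0. Without the arrays with Xist signal that median was -0.38 (adjusted p = 0.112), and in wild type, against its single day 0 array, it was 0.43 (adjusted p = 0.0404, and adjusted p = 0.269 with an estimated correlation), and 0.36 (adjusted p = 0.180) with a term for those arrays. The 3 measured erythrocyte genes did not pass and were too few to test as a list (median -0.06).

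Of the 21 lists that passed, 7 no longer did without the 2 arrays with Xist signal, which leaves the change in knockout alone. Among them were the ERK feedback, basal and suprabasal lists above, while the immediate-early and macrophage lists came to pass. Of 23 hair shaft and inner root sheath genes, Dsc2 rose, Dsg4 fell and 21 did not pass (likewise adjusted over the list alone). Their median was -2.27 (adjusted p = 0.000123, and adjusted p = 0.503 with an estimated correlation) over all arrays and 0.26 (adjusted p = 0.224) without the 2 arrays. Of 12 melanocyte genes, Mitf fell by 1.42 ± 0.16 (SE) and 0 rose (1 fell adjusted over the list alone). Their median was -1.45 (adjusted p = 0.000613, and adjusted p = 0.473 with an estimated correlation) and 0.24 (adjusted p = 0.298) without the 2 arrays. Of 16 matrix protease and plasminogen system genes, 4 rose and 0 fell (5 rose adjusted over the list alone), with Mmp9 at 4.45 ± 0.49 and Mmp13 at 4.44 ± 0.65 (SE). The median was 1.41 (adjusted p = 0.000908, and adjusted p = 0.497 with an estimated correlation), and 0.29 (adjusted p = 0.489) without the 2 arrays. Of 13 neutrophil genes, Trem1 rose by 1.79 ± 0.44 (SE) and 0 fell (0 and 0 adjusted over the list alone). Their median was 0.77 (adjusted p = 0.00998, and adjusted p = 0.503 with an estimated correlation), and 0.36 (adjusted p = 0.271) without the 2 arrays; it was 1.21 without knockout day 0 replicate 2 and 1.27 without knockout day 6 replicate 1.

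In wild type, against its single day 0 array, these and other lists had medians of 1.03 for basal keratinocyte (adjusted p = 1.08e-06), 2.64 for matrix protease and plasminogen system (adjusted p = 2.43e-12), 1.60 for neutrophil (adjusted p = 0.000183), 0.89 for endothelial (adjusted p = 0.000162), 0.34 for IQGAP family and Ras-ERK cascade (adjusted p = 0.00976) and -3.97 for melanocyte genes (adjusted p = 1.97e-18). With an estimated correlation 0 lists passed there (smallest adjusted p = 0.1997 with an estimated correlation). The IQGAP family and Ras-ERK cascade median was 0.16 (adjusted p = 0.361) with a term for the arrays with Xist signal and 0.57 without wild-type day 6 replicate 1, and the neutrophil median was 0.79 without that replicate. Lists that passed over both genotypes but not in wild type were DNA replication, fibroblast and collagen (median -0.14, adjusted p = 0.270), Langerhans and dendritic cell (-0.77, adjusted p = 0.0864), T cell (-0.13, adjusted p = 0.227), interferon-stimulated (-0.39, adjusted p = 0.0725) and Schwann cell and nerve genes (-0.34, adjusted p = 0.123).

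The day count was 4027 (1915 rose and 2112 fell) without the arrays with Xist signal, that is, in knockout alone. The count over both genotypes fell to 727 without knockout day 0 replicate 1, 1132 without replicate 2 of that group, 1013 without knockout day 6 replicate 1 and 849 without its replicate 2.

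**Figure D2:**
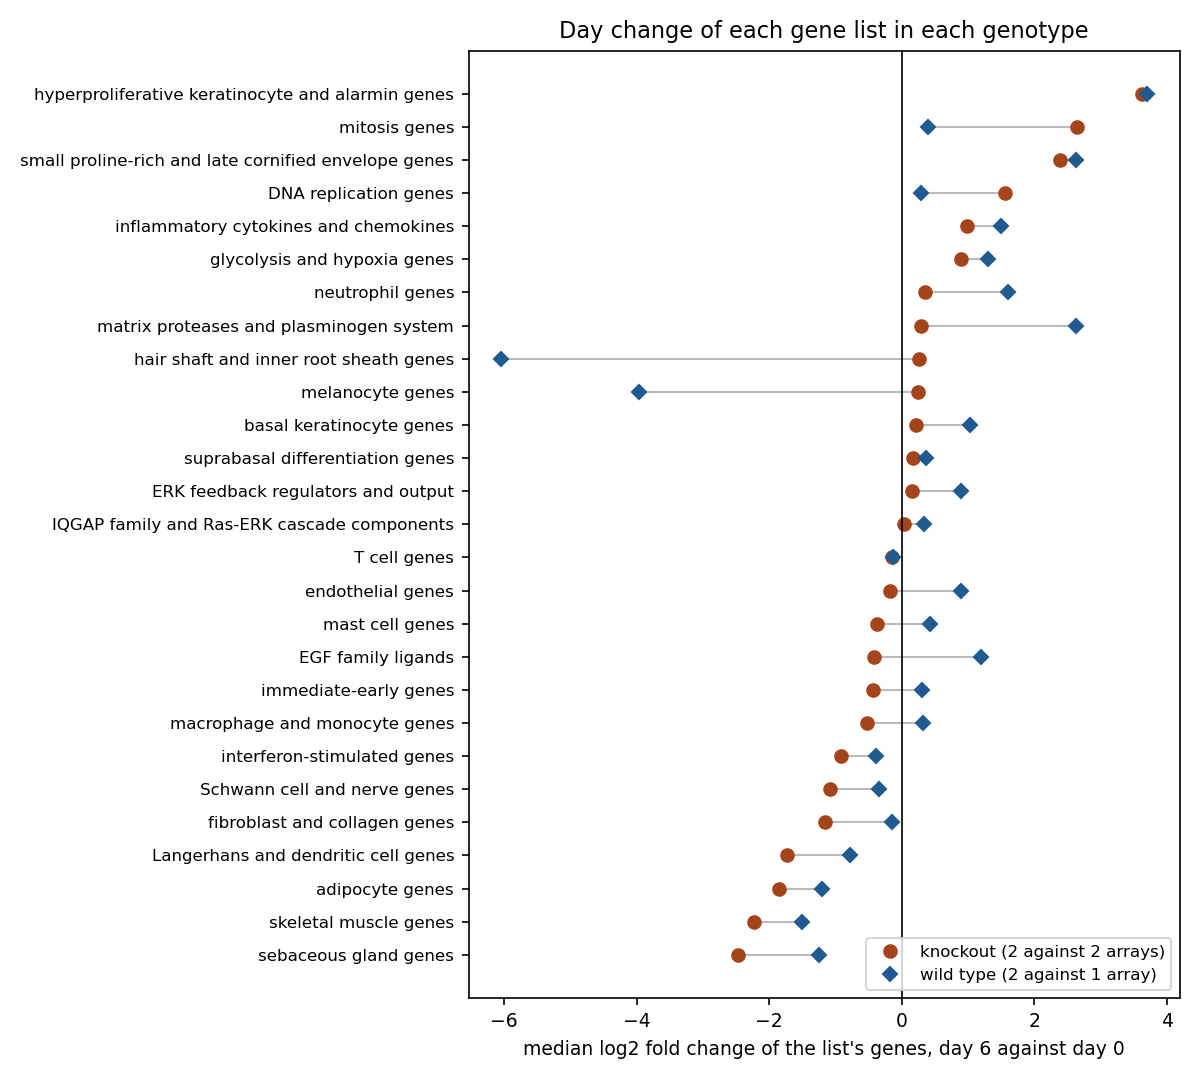
The median log2 fold change, day 6 against day 0, of the measured genes of each of the 27 tested lists (horizontal axis; lists on the vertical axis), in knockout (circles, 2 against 2 arrays) and in wild type (diamonds, 2 against 1 array). The 2 genotypes lie close for hyperproliferative keratinocyte and alarmin genes (3.62 and 3.71) and far apart for hair shaft and inner root sheath genes (0.26 and -6.05).

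Tmprss11b and Csta3 were among the 5 largest rises of the day change in each genotype. Tmprss11b rose by 6.97 ± 0.20 in knockout (2 against 2 arrays) and 6.94 ± 0.25 in wild type (2 against 1 array), and Csta3 by 6.06 ± 0.40 and 6.43 ± 0.49 (SE). The low level described above was reached in at least 1 array, at day 0 by Tmprss11b, Csta3, Stfa2, Defb4 and Lce3a in knockout and by Tmprss11b and Lce3e in wild type. At day 6 it was reached by Lep and Mylk4 in knockout and by Krt28, Krt26, Gprc5d and Krtap19-1 in wild type. The sizes in this paragraph are therefore fitted values and are not compared between genotypes. In knockout, Stfa2 (6.61 ± 0.37), Defb4 (6.60 ± 0.54) and Lce3a (6.35 ± 0.18, SE) were the other large rises, and Krt77 (-6.58 ± 0.25), Lep (-6.29 ± 0.17), Mylk4 (-6.07 ± 0.55), Serpina3b (-5.92 ± 0.24) and the complement gene C7 (-5.53 ± 0.30, SE) the largest falls. In wild type, Lce3e (7.13 ± 0.34), Sprr2d (6.32 ± 0.50) and Defb14 (6.27 ± 0.37, SE) were the other large rises. The largest wild-type falls were those of the inner root sheath keratins Krt28 (-7.74 ± 0.22) and Krt26 (-7.30 ± 0.25), Gprc5d (-7.33 ± 0.38), the hair keratin-associated gene Krtap19-1 (-7.26 ± 0.46) and Calhm4 (-7.29 ± 0.22, SE).

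By limma, 3251 genes changed in knockout (1443 rose, 1808 fell) and 1418 in wild type (699 rose, 719 fell). Simulated data recovered 53.1% of 2-fold changes in knockout and 22.5% in wild type, so the 2 counts do not compare the size of the response. There were 375 genes that rose in both, against 50.6 for independent lists, and 307 that fell in both, against 65.2. A further 40 genes were called in both with opposite signs. The fold changes correlated at r = 0.493 across genes, which are not independent replicates. At day 6 the 375 shared rises differed between knockout and wild type by a median of 0.05 and the 307 shared falls by 0.08. Mean levels of the mitosis list at day 0 were 6.19 and 6.38 in knockout and already 8.29 in the wild-type array. At day 6 they were 8.87 and 9.07 in knockout and 8.29 and 9.25 in wild type. The different day change of this list in the 2 genotypes, given next, therefore rests on the single wild-type day 0 array. All 23 mitosis genes rose in knockout (23 adjusted over the list alone; median 2.65, adjusted p = 3.96e-17, and adjusted p = 0.295 with an estimated correlation). In wild type 0 rose (0 adjusted over the list alone; median 0.39, adjusted p = 0.0161, and adjusted p = 0.643 with an estimated correlation), and the median was 0.05 (adjusted p = 0.624) with a term for the arrays with Xist signal and 0.90 without wild-type day 6 replicate 1. In wild type 21 of 23 hair shaft and inner root sheath genes fell (22 adjusted over the list alone; median -6.05, adjusted p = 7.19e-32, and adjusted p = 0.1997 with an estimated correlation). In knockout, 2 rose and 1 fell (likewise adjusted over the list alone; median 0.26, adjusted p = 0.290, and adjusted p = 0.798 with an estimated correlation). Skeletal muscle genes fell in 18 of 19 cases in knockout (median -2.23) and 11 of 19 in wild type (median -1.51), with 19 and 12 adjusted over the list alone. The camera adjusted p values were 4.96e-16 and 6.25e-11, with adjusted p = 0.295 and adjusted p = 0.294 with an estimated correlation. The knockout count was 1421 and 1935 without day 0 replicates 1 and 2 of that genotype and 1381 without its day 6 replicate 1. The wild-type count was 2209 without day 6 replicate 1.

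The next comparison, knockout against wild type at day 6 (n = 2 each), asked how loss of Iqgap1 altered the treated tissue. Mast cell genes were lower in knockout: all 10 had lower means, with a median log2 difference of -0.72, while 0 passed over all genes and 6 adjusted over the list alone. The list passed camera (adjusted p = 1.82e-09), but not with an estimated correlation (adjusted p = 0.174 with an estimated correlation). That estimate was -0.068, below the preset 0.01, so correlated members do not account for the higher p. With an estimated correlation camera uses only the 3 residual degrees of freedom of this fit, which raises p. The rotation test fry, which does not compare a list with other genes, called the mast cell list in one direction (fry adjusted p = 0.000919). The mast cell tryptase genes Tpsb2 and Tpsab1 were at -1.02 ± 0.16 and -1.04 ± 0.19, the chymase gene Mcpt4 at -0.84 ± 0.16 and the carboxypeptidase gene Cpa3 at -0.78 ± 0.20 (SE). Mean levels of the list were 6.20 and 6.24 in the knockout arrays and 6.83 and 6.85 in the wild-type arrays. No single gene of the genome passed in either direction.

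By limma, 0 of 19937 genes changed at an adjusted p under 0.05; 1182 had an unadjusted p under 0.05, where 997 would by chance. The 5 smallest p belonged to Iqgap1, Mcpt2 (-1.57 ± 0.19), Tmprss2 (-1.39 ± 0.17), Csf3 (-1.44 ± 0.19) and Slit1 (1.26 ± 0.17, SE), none of them past the threshold (adjusted p = 0.503 for each). Mcpt2, a mast cell protease gene, is not in the mast cell list. It lay at 3.47 and 3.43 in the knockout arrays of day 6, under the low level described above, so its size is only a fitted value. Iqgap2 (0.02 ± 0.31) and Iqgap3 (0.67 ± 0.48, SE) did not pass. In simulated data of this design, 55.4% of 2-fold and 98.8% of 4-fold differences were recovered. Those data held 200 changed genes. With fewer real changes the adjusted threshold is stricter, so recovery may be overstated for this comparison. Iqgap1, 3.31-fold lower with the smallest p, did not pass. Without wild-type day 6 replicate 2, 43 genes passed (13 higher and 30 lower in knockout), among them Xist, Eif2s3y, Kdm5d and Uty and hair genes such as Krtap15 (-4.41 ± 0.15) and Krt25 (-2.64 ± 0.20, SE), both chosen after their values were seen.

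The mast cell median was -0.71 against wild-type replicate 2 alone (adjusted p = 2.43e-11, and adjusted p = 0.472 with an estimated correlation). Macrophage and monocyte genes were lower by a median of -0.23 (adjusted p = 0.0399, and adjusted p = 0.822 with an estimated correlation), with Lyz2 at -0.51 ± 0.19 and C1qa at -0.48 ± 0.22 (SE). That median was 0.08 without knockout day 6 replicate 1, and its adjusted p was 0.418 without wild-type day 6 replicate 2. In 6 other lists that passed, the call was lost or the median turned within the arrays without Xist signal. Medians were 0.55 for fibroblast and collagen genes (adjusted p = 0.00188), 0.41 for endothelial genes (adjusted p = 0.00595) and 0.28 for skeletal muscle genes (adjusted p = 0.000763). They were -0.41 for matrix protease and plasminogen system genes (adjusted p = 0.0465), -0.38 for neutrophil genes (adjusted p = 0.0193) and -0.20 for inflammatory cytokine and chemokine genes (adjusted p = 0.0249). With an estimated correlation the adjusted p = 0.740 for the cytokine list and adjusted p = 0.822 for the other 5. Within the arrays without Xist signal the medians were 0.19, 0.16, -0.06, -0.04, -0.11 and 0.00 in the order given. The cytokine list still passed there (adjusted p = 0.0110, and adjusted p = 0.826 with an estimated correlation), and the other 5 did not. Knockout day 6 replicate 2 exceeded replicate 1 by a median of 0.91 in fibroblast and collagen genes and 0.93 in endothelial genes. Without that replicate 2 these 2 medians were 0.07 and 0.01 (adjusted p = 0.891 for each), and the muscle list no longer passed (adjusted p = 0.114). Without replicate 1 the matrix protease, neutrophil and cytokine lists no longer passed (adjusted p = 0.328, 0.549 and 0.349). Adjusted over the list alone, 2 skeletal muscle genes were higher and 1 cytokine gene was lower, and 0 of the other 4 lists or of the macrophage list passed.

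The other 19 tested lists did not pass. Ras-ERK groups were among them: the median was -0.01 for ERK feedback regulators and output genes (adjusted p = 0.605), 0.05 for IQGAP family and Ras-ERK cascade genes (adjusted p = 0.30), -0.01 for immediate-early genes (adjusted p = 0.866) and -0.35 for EGF family ligands (adjusted p = 0.125). Mitosis genes had a median of 0.17 (adjusted p = 0.186), small proline-rich and late cornified envelope genes 0.17 (adjusted p = 0.125) and hyperproliferative keratinocyte and alarmin genes -0.03 (adjusted p = 0.605). Against wild-type replicate 2 alone, within the arrays without Xist signal, 7 of the 19 came to pass. Their medians were -0.23 for mitosis genes (adjusted p = 5.69e-06), -0.19 for DNA replication genes (adjusted p = 0.000515), -0.41 for sebaceous gland genes (adjusted p = 0.000269), 0.21 for melanocyte genes (adjusted p = 0.000499), -0.24 for the ERK feedback list (adjusted p = 0.00300), 0.19 for the small proline-rich list (adjusted p = 0.0166) and -0.31 for EGF family ligands (adjusted p = 0.0494). With an estimated correlation the adjusted p = 0.915 for the small proline-rich list and adjusted p = 0.826 for the other 6. The medians of the IQGAP, immediate-early and hyperproliferative lists turned to -0.04, 0.01 and 0.00 there (adjusted p = 0.361, 0.848 and 0.793).

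**Figure D3:**
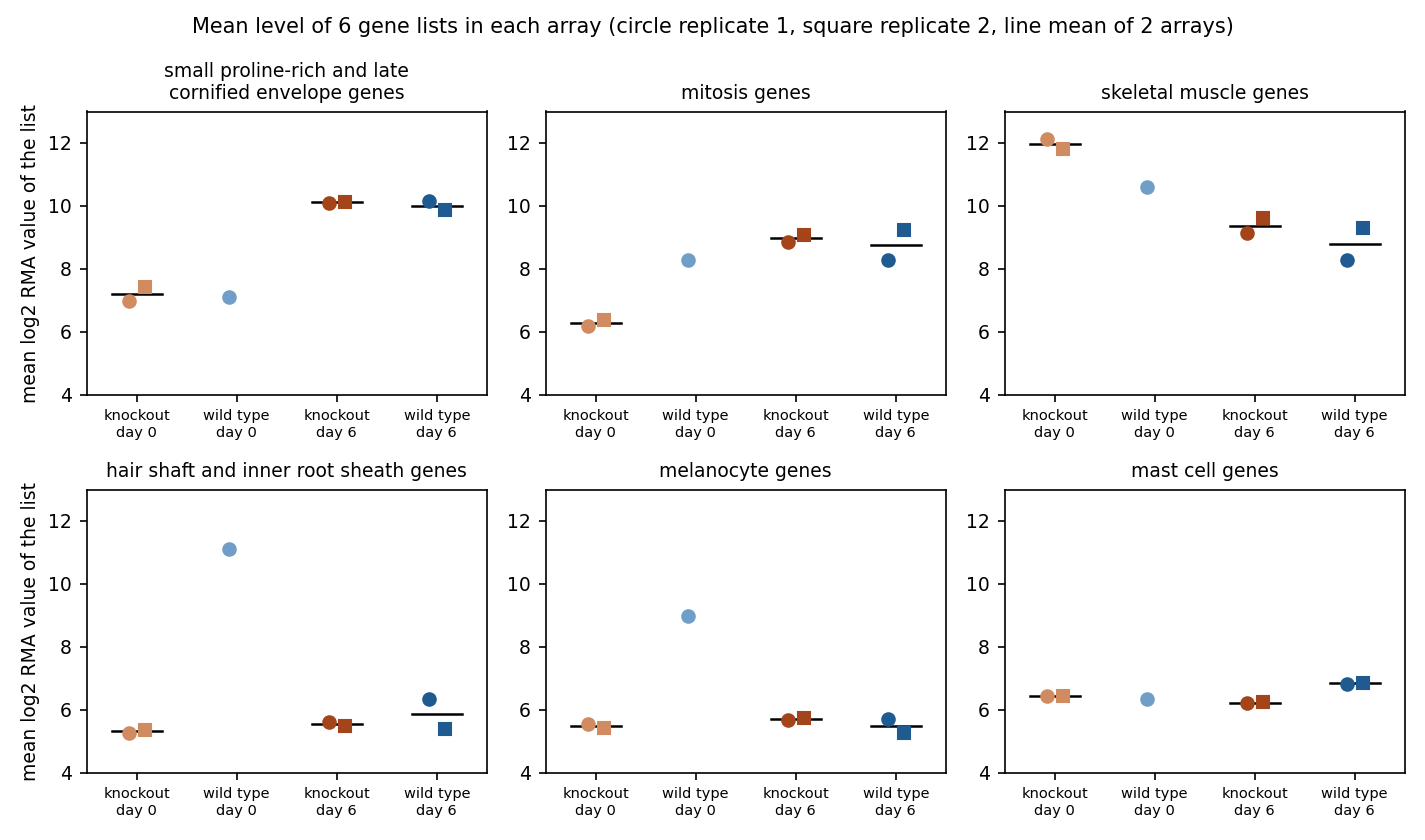
The mean log2 RMA value (vertical axis) over the measured genes of 6 lists in each of the 7 arrays, by group (horizontal axis); circles are replicate 1, squares replicate 2, and lines the mean where a group has 2 arrays. Hair shaft and inner root sheath genes stand at 11.12 in the wild-type day 0 array and at 5.28 to 6.33 in the other 6, and mast cell genes at 6.20 and 6.24 in knockout against 6.83 and 6.85 in wild type at day 6.

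Over both days together, knockout was compared with wild type with the day as a term (n = 4 and 3 arrays). Iqgap1 was 2.66-fold lower in knockout (-1.41 ± 0.21, SE). The other genes with the smallest p were Sectm1a (1.98 ± 0.27), the thyroid hormone receptor gene Thrb (0.93 ± 0.13), the transporter gene Abcc3 (1.09 ± 0.16) and the muscle gene Ttn (3.05 ± 0.44, SE), all higher in knockout. Neither these genes (adjusted p = 0.239 for each) nor Iqgap2 (0.75 ± 0.42) or Iqgap3 (0.24 ± 0.42, SE) passed. By limma, 0 of 19937 genes changed, and 3729 had an unadjusted p under 0.05. The additive fit assumes the same genotype difference on both days, and a difference that varies with day enters its residual. Since 619 genes passed for a difference in change, this 0 does not show that the genotypes are alike. The count was 836 without wild-type day 6 replicate 2, and 2355 when the differences of the 2 days were averaged from the 4 group means in place of the additive fit.

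Of the 27 lists, 16 passed camera over both days, 11 higher and 5 lower in knockout, and 0 with an estimated correlation (smallest adjusted p = 0.657 with an estimated correlation). The largest medians were -2.72 for hair shaft and inner root sheath genes (adjusted p = 4.41e-07), -1.39 for melanocyte genes (adjusted p = 0.00546), 0.98 for fibroblast and collagen genes (adjusted p = 5.33e-06) and 0.80 for endothelial genes (adjusted p = 1.95e-06). Adjusted over the list alone, 9 fibroblast and collagen genes passed and 0 of the other 3 lists. Leaving out the arrays with Xist signal also removed the only wild-type day 0 array. Knockout was then set against wild-type day 6 replicate 2 alone, so the result was that of day 6. The medians were 0.18, 0.21, 0.19 and 0.16 in that order, so the hair and melanocyte medians turned once wild-type day 0 was gone. The number of lists past the threshold was 8 without the wild-type day 0 array, 10 without the arrays with Xist signal and 4 with a term for them.

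At day 0, the comparison set 2 knockout arrays against a single wild-type array, which was assumed to vary like the other groups. That array also differed from both knockout arrays in Xist and Y-linked signal, so no difference below can be credited to genotype alone. Hair shaft genes had higher values in that wild-type array than in the knockout arrays. Krtap15, Krtap6-1, Krtap8-1 and Krtap7-1, which encode keratin-associated proteins of the hair shaft, and Prr9 stood lowest in knockout against wild type. Krtap8-1 and Krtap7-1 were lower in knockout by log2 differences of -8.27 ± 1.15 and -8.19 ± 1.47 (SE). Krtap15, Krtap6-1 and Prr9 were lower too, but lay between 3.29 and 4.16 in the knockout arrays, at or under the low level described above, against 11.79 to 12.62 in wild type, so no size is given. Genes higher in knockout were the complement gene C7 (51.7-fold) and the muscle genes Ankrd1 (47.6-fold), Xirp1 (33.4-fold), Alpk2 (24.5-fold) and Klhl40 (23.1-fold). Iqgap1 was lower in knockout (-0.94 ± 0.24), Iqgap2 was higher (1.85 ± 0.38), and Iqgap3 did not pass (-0.42 ± 0.58, SE).

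By limma, 2869 genes changed at day 0, 1701 higher and 1168 lower in knockout; with arrays centred on expressed genes the split was 1382 higher and 1645 lower. Centring moved the median difference of all genes from -0.09 to -0.27. In this fit, a term for the arrays with Xist signal is the difference between the 2 wild-type day 6 arrays, carried over to day 0. It holds any other difference between those 2 samples as well. With that term the count was 682. It was 1239 and 1282 without knockout day 0 replicates 1 and 2, and 4328 without either wild-type day 6 array. Of 23 hair shaft and inner root sheath genes, 22 were lower (23 adjusted over the list alone; median -6.58, adjusted p = 8.01e-26, and adjusted p = 0.366 with an estimated correlation). Of 12 melanocyte genes, 9 were lower (11 adjusted over the list alone; median -4.19, adjusted p = 1.77e-11, and adjusted p = 0.366 with an estimated correlation). Of 23 mitosis genes, 12 were lower (18 adjusted over the list alone; median -1.77, adjusted p = 3.06e-11, and adjusted p = 0.366 with an estimated correlation; -3.21 with the Xist term). Of 15 endothelial genes, 6 were higher (13 adjusted over the list alone; median 1.36, adjusted p = 3.53e-07, and adjusted p = 0.372 with an estimated correlation). Of 19 skeletal muscle genes, 7 were higher (7 adjusted over the list alone; median 1.12, adjusted p = 1.75e-06, and adjusted p = 0.377 with an estimated correlation); with the Xist term the muscle median was 0.14 (adjusted p = 0.129) and the list no longer passed.

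The last comparison asked whether the day 6 against day 0 change itself differed between genotypes; a positive value means a higher change in knockout. The largest positive differences were those of Prr9 (8.55 ± 0.82), Crnn (8.54 ± 0.36), Krt28 (7.65 ± 0.28), Krtap19-1 (7.49 ± 0.60) and Gprc5d (7.43 ± 0.49, SE). Each was at 11.35 to 12.30 in the wild-type day 0 array and at 3.23 to 4.64 in the knockout arrays of that day. There all but Crnn lay at or under the low level described above, so the sizes and their order are those of fitted values. The largest negative differences were C7 (-5.42 ± 0.48), the muscle genes Xirp1 (-4.24 ± 0.47), Alpk2 (-3.80 ± 0.74) and Musk (-3.41 ± 0.53), and Cyp2e1 (-3.75 ± 0.69, SE). Iqgap1 (-0.78 ± 0.31), Iqgap2 (-1.83 ± 0.49) and Iqgap3 (1.10 ± 0.76, SE) did not pass.

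By limma, 619 genes differed in their change (350 positive, 269 negative). All of this rests on the single wild-type day 0 array. The count was 747 with a term for the arrays with Xist signal, 285 and 323 without knockout day 0 replicates 1 and 2, 143 and 237 without knockout day 6 replicates 1 and 2, and 1038 without wild-type day 6 replicate 1. Of 23 hair shaft and inner root sheath genes 19 differed (23 adjusted over the list alone; median 5.98, adjusted p = 5.91e-34, and adjusted p = 0.233 with an estimated correlation), and of 12 melanocyte genes 9 (10 adjusted over the list alone; median 4.197, adjusted p = 9.15e-16, and adjusted p = 0.233 with an estimated correlation). Of 23 mitosis genes 10 differed (17 adjusted over the list alone; median 2.38, adjusted p = 1.72e-15, and adjusted p = 0.309 with an estimated correlation). Small proline-rich and late cornified envelope genes had a median of 0.01, with 1 of 26 past the threshold (2 adjusted over the list alone; camera adjusted p = 0.601). Simulated data of this design recovered 5.22% of 2-fold and 78.8% of 4-fold differences in change.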

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

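The tests of hair genes and of muscle and fat genes were chosen only after the result was seen; those of other splits of the arrays and of the neighbourhood of Iqgap1 were planned.

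The difference between genotypes in the day change passed the test in 619 genes, which drew attention because it compares the day change of the 2 genotypes. Its wild-type day 0 arm was 1 array, which also differed from the knockout arrays in Xist and Y-linked signal, so a differing response of the genotypes does not follow. The genes with the largest fitted differences were Prr9 (8.55), Crnn (8.54), Krt28 (7.65), Krtap19-1 (7.49), Gprc5d (7.43), C7 (-5.42), Xirp1 (-4.24), Alpk2 (-3.80), Cyp2e1 (-3.75) and Musk (-3.41). Among lists that passed, median differences were 5.98 for hair shaft and inner root sheath genes, 4.197 for melanocyte genes, 2.38 for mitosis genes and 1.28 for DNA replication genes. They were -0.33 for IQGAP family and Ras-ERK cascade genes, -0.54 for ERK feedback regulators and output genes, -0.56 for immediate-early genes and -1.60 for EGF family ligands. Among skin and stroma lists they were -0.91 for basal keratinocyte, -1.27 for fibroblast and collagen, -1.86 for matrix protease and plasminogen system, -1.02 for endothelial, -0.58 for Schwann cell and nerve and -0.57 for glycolysis and hypoxia genes. Among immune lists they were -1.24 for cytokine and chemokine, -0.98 for macrophage and monocyte, -1.08 for neutrophil, -0.86 for Langerhans and dendritic cell, -0.80 for mast cell and -0.73 for interferon-stimulated genes. Adipocyte genes had -0.63 and skeletal muscle genes -0.60. With a term for the arrays with Xist signal 4 of these lists no longer passed: IQGAP family and Ras-ERK cascade (-0.08, adjusted p = 0.296), ERK feedback (-0.35, adjusted p = 0.0562), interferon-stimulated (-0.71, adjusted p = 0.0782, and -0.11 with adjusted p = 0.447 without knockout day 0 replicate 2) and skeletal muscle genes (-0.14, adjusted p = 0.131). Leaving out 1 array moved other medians by over 1.5 times. Without knockout day 6 replicate 1 they were -0.53 for neutrophil and -0.38 for adipocyte genes (adjusted p = 0.0573 for each, no longer passing), -0.22 for Langerhans and dendritic cell, -0.49 for macrophage and monocyte, -0.80 for fibroblast and collagen, -0.60 for endothelial and -0.88 for Schwann cell and nerve genes. Without wild-type day 6 replicate 1 they were -0.62 for cytokine and chemokine, -0.53 for neutrophil (adjusted p = 0.213, no longer passing) and -1.09 for skeletal muscle genes, and without knockout day 0 replicate 2 -0.60 for basal keratinocyte genes. Without knockout day 6 replicate 2 they were -1.75 for neutrophil, -1.17 for adipocyte and -0.37 for Schwann cell and nerve genes. With an estimated correlation 0 of the 22 lists passed (smallest adjusted p = 0.233 with an estimated correlation). All of these differences share the single wild-type day 0 array.

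Hair shaft and inner root sheath genes stood a median of 6.58 higher in that wild-type array than in knockout at day 0, and 42 of 44 hair keratin-associated genes outside the list were lower in knockout (median -6.19). An effect of the Iqgap1 genotype stays open: knockout minus wild type at day 6 had a median of -0.21 (interquartile range -0.52 to 0.01), and of 0.18 against wild-type replicate 2 alone, but 19 of the 23 hair genes then lay below the median level of all genes in both genotypes, where a difference can be hidden. A feature shared by the 2 arrays with Xist signal stays open: at day 6 wild-type replicate 1 exceeded replicate 2 by a median of 0.70 in the hair list (interquartile range 0.52 to 1.02) and 1.06 in the 44 keratin-associated genes (0.79 to 2.03, 42 genes higher), less than at day 0 but in the same direction. A growing phase of the hair follicles in the wild-type day 0 sample also stays open, as a hypothesis: mitosis genes, none of them in the hair list, were also lower in knockout at day 0 (median -1.77, interquartile range -2.65 to -1.32, 23 of 23 genes; median -3.21 with the term for the arrays with Xist signal). With 1 array, a different body site, age or animal could not be tested.

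Skeletal muscle and adipocyte genes were lower at day 6 in knockout by medians of -2.23 and -1.85. An even dilution of all other cells by keratinocytes was argued against by the 1 list tested. Endothelial genes had a median of -0.18, which was 2.05 above muscle (permutation p = 6.0e-05 across genes, which are not independent replicates). Their day 6 means differed between replicates (8.10 and 8.92, against 8.76 in each at day 0). Not tested were Langerhans and dendritic cell (-1.74), fibroblast and collagen (-1.16), Schwann cell and nerve (-1.08), macrophage and monocyte (-0.53), mast cell (-0.38), T cell (-0.15), melanocyte (0.24) and neutrophil genes (0.36). Whether the day 6 samples held less of the muscle and fat layer, or muscle and fat cells changed their expression, cannot be told apart: muscle genes fell by uneven amounts (interquartile range 1.61, median standard error 0.30), but the fall was smaller in genes with a higher day 0 level (Spearman rho of 0.43 between level and log2 change). The labels do not describe the depth of the tissue taken.

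Strain DNA kept around the deleted Iqgap1 gene may differ between knockout and wild type in a mixed background. Of 140 genes within 10 Mb of Iqgap1, 6 had an unadjusted p under 0.01 for genotype over both days (4.29%), against 787 of 19777 elsewhere (3.98%). Fisher's exact p was 0.826, and the odds ratio of 1.08 had a 95% interval of 0.388 to 2.42, too wide to tell an enrichment apart from none.

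For the day change over both genotypes, 1 of 34 splits of the 7 arrays into 3 and 4, the real one, gave as many genes (2286, against 8 in the highest other split). The smallest share that 34 splits can give is 1 of 34. Other splits were fitted without the real day term, so the day difference stayed in their residual and few calls were likely. Chance is therefore not excluded. Where replicates may share a mouse, as in knockout, chance between mice stays untested. For genotype over both days the real count by limma was 0, with 3729 genes at an unadjusted p under 0.05, and the highest other count was 0. All 34 of 34 splits then give as many by construction, so this count says nothing about chance.

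Among 13120 probe sets without a single gene symbol, which were tested only in the setting with all probe sets, 280 changed between day 0 and day 6 there (154 rose and 126 fell).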

How the results depend on the processing

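The term for the 2 arrays with Xist signal, and leaving them out, were tests chosen only after the result was seen; the others were planned.

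Named genes kept direction and side of the threshold in 3798 comparisons with an alternative; 190 kept direction but no longer passed, 61 came to pass and 22 changed sign. For lists that had passed these were 1262 kept, 388 no longer passing and 23 changing sign; lists that had not passed came to pass in 147 of 986 comparisons. Counts of genes stayed within 1.5 times in 109 cases and moved further in 38; counts of lists did so in 78 and 21. Signal over background limits weakly expressed genes, and 7 arrays limit all: leaving 1 out often left a group with a single array, assumed to vary like the others. No value was possible without the wild-type day 0 array, or without the arrays with Xist signal, for the day change in wild type, for genotype at day 0 or for the difference in change. Array weights did not converge for some fits. Unless an alternative's own construction (another threshold, fewer genes or fewer arrays) shows it, the cause was not tested.

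Day change over both genotypes: 1395 genes with a fold of 2 or more as well, 567 at an adjusted p under 0.01, 3564 at 0.10, 5718 with array weights, 3742 with averaged group-mean differences and 4027 without the arrays with Xist signal. At thresholds of 0.01 and 0.10, the difference in change had 138 and 1236 genes, the wild-type day change 493 and 2269 and genotype at day 0 795 and 4579; the knockout day change had 1431 at 0.01. Genotype over both days gave 2355 with averaged group-mean differences. Genotype at day 6 gave 1 with all probe sets. Genotype at day 0 gave 4609 with array weights, 4978 from its own groups and 682 with the Xist term. The difference in change gave 341 with genes above the median level.

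Without each array in turn, genes ranged from 727 to 3251 for day, 0 to 836 for genotype, 1381 to 4027 for day in knockout, 1040 to 2209 for day in wild type, 0 to 43 for genotype at day 6, 1239 to 4328 at day 0 and 143 to 1038 for the difference in change. By limma the zeros stand beside 3729 and 1182 genes at an unadjusted p under 0.05. Lists ranged from 15 to 22, 8 to 19, 15 to 17, 16 to 21, 8 to 11, 18 to 20 and 18 to 24 in that order.

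With an estimated correlation 0 lists passed in every comparison. With fry in one direction 8 passed for day, 0 for genotype, 1 for genotype at day 6 (mast cell genes) and 5 for the difference in change. With fry in either direction these were 23, 1, 3 and 16 in that order. For genotype over both days 7 passed with genes above the median level, 4 with the Xist term and 10 without those arrays.

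Signs changed as follows. For day, Iqgap1 was 0.0142 with averaged group-mean differences, and without the arrays with Xist signal Mlana was 0.0295, Oca2 0.218, hair genes 0.262 and melanocyte genes 0.239. Without each array in turn Iqgap1 ranged from -0.378 to 0.0351, Mlana from -1.99 to 0.0295, Oca2 from -1.89 to 0.218, hair genes from -2.97 to 0.262 and melanocyte genes from -1.91 to 0.239. For genotype with the Xist term, Iqgap2 was -0.0314, Iqgap3 -0.165, IQGAP family and Ras-ERK cascade genes -0.0407 and muscle genes -0.0577. Leaving those arrays out left wild-type day 6 replicate 2 as the only wild-type array. Then Iqgap2 was -0.285, IQGAP family and Ras-ERK cascade genes -0.0382, hair genes 0.176, muscle genes -0.0648, melanocyte genes 0.208 and glycolysis genes -0.000275. Without each array in turn Iqgap3 ranged from -0.162 to 0.674, immediate-early genes from -0.0125 to 0.417, mitosis genes from -1.03 to 0.166 and melanocyte genes from -2.05 to 0.0780. For genotype at day 6, Iqgap2 was -0.0389 with centring, and cytokine genes were 0.0834 with genes above the median level. With the Xist term, and equally without those arrays, Iqgap2 was -0.285, Casq1 -0.00665, muscle genes -0.0648 and cytokine genes 0.00194. Without each array in turn Iqgap2 ranged from -0.373 to 0.412, Casq1 from -0.00665 to 2.09, C1qc from -1.27 to 0.0345, muscle genes from -0.0648 to 0.601, cytokine genes from -0.448 to 0.00194 and macrophage genes from -0.635 to 0.0814.

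The replicate block gave 1745 genes for day, 3523 for day in knockout, 1234 for day in wild type, 2400 for genotype at day 0, 613 for the difference in change, and 0 by limma for genotype over both days and at day 6. The median day change of suprabasal genes in wild type turned to -0.0342. Deviations of same-numbered arrays correlated across genes at 0.086, 0.037 and 0.227 over the pairs of the 3 groups with 2 arrays. The lone wild-type day 0 array has no such deviation; it correlated most with wild-type day 6 replicate 1 (0.937, against 0.924 to 0.927), so shared numbers are not excluded as pairs.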

Other observations

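No further test was chosen only after the result was seen; the values below were picked after they were seen.

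Replicates of a group differed in some gene groups. In knockout at day 0, interferon-stimulated genes were a median of 1.16 higher in replicate 2 than in replicate 1, and in knockout at day 6 they were 0.83 higher. Sebaceous gland genes were 1.45 higher in knockout day 6 replicate 2, with endothelial genes 0.93, fibroblast and collagen genes 0.91 and neutrophil genes 1.07 higher in the same array. Neutrophil genes were also 0.79 higher in knockout day 0 replicate 2. In wild type at day 6, replicate 1 was lower than replicate 2 in mitosis genes (-0.89) and skeletal muscle genes (-0.91), and higher in neutrophil genes (0.96).

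Mast cell genes differed little between replicates: 0.03 in wild type at day 6, -0.02 in knockout at day 0 and -0.05 in knockout at day 6. Their means at day 0 were 6.43 in each knockout array and 6.34 in wild type. Genes that differed by 2-fold or more between replicates numbered 266 in knockout at day 0, 350 in knockout at day 6 and 745 in wild type at day 6.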
